A study of Mus musculus with 4 samples.

How the data were processed

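The deposited count matrices hold raw UMI counts per gene and nucleus, written by Cell Ranger 7.0.0 per the file headers, for 4 libraries of 32285 genes each. The authors' processing notes also name GRCm38, Seurat 4.3.0 and R 4.3.0 without giving their role. Aligner options, the intron setting, the annotation release and the pooling of animals are not stated. Nuclei were prepared by the authors from dorsal horn tissue on a sucrose gradient, and libraries were made with 10x Genomics 3' chemistry. The matrices hold called barcodes only, 112746 in all, so free RNA in empty droplets could not be measured and no background was subtracted. Of 32285 genes, 32235 matched GENCODE vM21 by Ensembl ID, which gave the GRCm38 coordinates. Groups were taken from the sample titles, which the treatment tag contradicts for 2 libraries.

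Nuclei with at least 300 genes and under 5% mitochondrial UMIs were kept, which removed 552 of 112746 barcodes. Doublets were predicted in each library with scrublet as built into scanpy, at an expected share of 10%, 2 simulated doublets per nucleus and the automatic threshold. In the knockout SNI library that threshold marked under 0.5%, so scores above the 90th percentile were marked there, under 10% of nuclei because scores are tied. Marked shares were 3.03%, 11.3%, 9.82% and 9.34%, and 19096, 33244, 24451 and 25285 nuclei remained in the order wild-type naive, knockout naive, wild-type SNI and knockout SNI. Counts of genes seen in at least 20 nuclei were log-normalised, and 3000 variable genes were chosen with the library as batch key; genes of every list, mitochondrial genes and Malat1 were left out of them. Then came 40 principal components of scaled values, 20 nearest neighbours, a shared-neighbour graph with weights of at least 1 in 15, and Leiden clustering at resolution 1 on the 4 libraries together, without batch correction. A cluster of at least 50 nuclei took a class name when at least 66.7% of the fixed markers, and at least 3, were 2-fold or more above other nuclei with a UMI in at least 2% of its nuclei, and the mean log2 fold was at least 1. It stayed unnamed if its median doublet score was 0.2 or more, if haemoglobin was among its 10 leading genes, if a second class had 50% of its markers raised at a mean log2 fold of 0.8, or if its leading genes held more markers of another class. Neurons were instead called excitatory or inhibitory where the 2 marker means differed by at least 0.8 log2 units.

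Raw UMIs were summed over the nuclei of each class and library and given as CPM on the class total without mitochondrial genes. Levels have exact Poisson 95% intervals, ratios the exact conditional binomial interval, and shares Clopper-Pearson intervals. A count of 0 was set to a floor of 3 UMIs in ratios, which then rest on that floor and are not 95% limits. The 4 contrasts were knockout to wild type (KO to WT) in naive and in SNI libraries, and SNI to naive in wild type and in the knockout. The difference of the 2 injury log2 ratios was taken as knockout minus wild type and was not tested. For shares of nuclei with a Gpr37l1 UMI, every nucleus was thinned to 1000 UMIs and shallower ones were left out. Correlations across genes used genes with at least 200 UMIs over the 4 libraries, and the 2 contrasts of each correlation share no library. Classes, fixed beforehand but for oligodendrocyte cluster 7, were compared at 50 or more nuclei per library. Committed oligodendrocyte precursors were omitted.

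The gene lists, marker genes, contrasts, naming rule and alternatives were fixed before the data were examined. The lists cover astrocyte glutamate, GABA and potassium handling, reactive astrocyte genes, astrocyte synaptogenic and phagocytic genes, cytokine, chemokine and NF-kB genes, interferon response, immediate early genes, heat shock and unfolded protein, and glucocorticoid and circadian genes. Further lists cover cholesterol synthesis, the GPR37 family with its proposed ligand, partners and pro-resolving receptors, homeostatic and injury-activated microglia, oligodendrocyte injury response, neuropeptides and receptors, neuronal excitability, endothelial barrier, cell cycle and sex-linked genes. A list's median log2 ratio was taken over members with at least 50 UMIs over the 2 libraries compared, where at least 3 qualified, with a 95% interval from 1000 Poisson redraws of the counts. Its percentile is the share of 10000 random lists of the same size, matched in windows of 100 genes on mean expression, with a lower median; it is a description of these libraries and not a test. Named genes follow a rule in 4 parts: (a) Gpr37l1 and Gpr37 in every library; (b) up to 4 members of each list with the largest absolute log2 ratio in a contrast, in the classes the list fits. Part (c) is, in astrocyte-like nuclei, the 10 highest and 10 lowest genes per factor with 1 sign in both contrasts, ranked by the smaller absolute ratio, and the 5 highest and 5 lowest in each other class; part (d) is the 5 highest and 5 lowest differences of the injury ratios in astrocyte-like nuclei. Parts (c) and (d) used genes with at least 200 UMIs over the 4 libraries and left out mitochondrial and sex-linked genes; markers and leading genes of a class are not reported as results in it. A few genes that the rule picked are not reported here. A few genes that ranked below the top 4 of a list, and the fixed markers given as background, are named for context and were chosen after their values were seen.

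In simulated libraries with the depths of the astrocyte-like nuclei, 200 of 5089 genes were changed 2- or 4-fold up or down. All had the right sign, and counting intervals covered the true ratio for 94 to 98%. Smaller changes were not simulated. The simulated genotype and injury correlations were 0.658 and -0.00362 when genes were changed by genotype alone, and the 10 genes named in each direction had all been changed. Steps were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and scaling factors in R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.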

Results

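The study asks what loss of Gpr37l1 does to cells of the mouse spinal cord, without injury and 1 day after spared nerve injury (SNI), a model of neuropathic pain. Gpr37l1 is a G protein-coupled receptor found mainly in astrocytes. Single nuclei of the spinal dorsal horn were counted in 4 libraries, 1 for each group: wild-type naive, Gpr37l1 knockout naive, wild-type SNI and knockout SNI. Values given as a series of 4 follow that order. With 1 library per group there are no replicates, so no test was possible; an additive model over the 4 libraries would use the interaction of genotype and injury as its only error and was not run. Ratios are therefore descriptions of these libraries, and the 95% intervals in parentheses cover counting error only, not the variation between animals. The libraries held 19942, 37552, 27233 and 28019 barcodes with 35197290, 69572640, 50605908 and 44079044 UMIs, and the lowest total of a barcode was 500, 640, 500 and 500 UMIs. Median UMIs per barcode were 1438, 1509, 1484 and 1284. A treatment tag in the sample labels contradicts the sample titles: it gives SNI for the knockout naive library and naive for the wild-type SNI library. Groups follow the titles, which match the library names; if the tags held instead, both wild-type libraries would be naive and both knockout libraries injured, so genotype and injury could not be separated.

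All 4 libraries carried Y-linked transcripts and almost no Xist, as male tissue does. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were present in each; Ddx3y stood at 49.8, 58.7, 54.6 and 55.7 CPM (UMIs scaled to a common total per class) over all kept nuclei, and Xist, which the inactive X chromosome of females expresses, had 3, 11, 18 and 6 UMIs. The median KO to WT log2 ratio of the sex-linked list in astrocyte-like nuclei was 0.18 in naive and -0.05 in SNI libraries.

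Clusters were named by fixed marker genes, which gave astrocyte-, microglia-, oligodendrocyte-, oligodendrocyte precursor-, excitatory neuron- and inhibitory neuron-like nuclei in every library. Astrocyte-like nuclei, marked by genes such as Aqp4 and Gja1, made up 5.04% (4.74 to 5.36) of kept nuclei in the wild-type naive library, 3.56% (3.37 to 3.77) in the knockout naive, 5.33% (5.05 to 5.62) in the wild-type SNI and 7.35% (7.03 to 7.68) in the knockout SNI library. Microglia-like shares were 2.61%, 1.80%, 1.94% and 3.59%, oligodendrocyte-like shares 16.02%, 15.4%, 10.9% and 11.9%, and precursor-like shares 2.05%, 1.86%, 1.81% and 2.06%. Neurons were the most numerous, with excitatory shares of 21.4%, 19.4%, 15.2% and 21.4% and inhibitory shares of 11.6%, 10.3%, 8.49% and 11.8%. A further cluster, here called oligodendrocyte cluster 7, carried oligodendrocyte markers but was held apart because its leading genes included more markers of another class; its shares were 6.65%, 2.61%, 4.90% and 5.90%. Nuclei left unnamed made up 32.7%, 42.5%, 48.4% and 33.2% apart from that cluster. The unnamed cluster 1, led by the abundant cytoplasmic transcripts of Actb, Aldoc and Gapdh, held 86, 4596, 4573 and 233 nuclei and so lay almost wholly in the knockout naive and wild-type SNI libraries. Oligodendrocyte-like nuclei fell into cluster 2 (3013, 278, 2585 and 2794 nuclei) and cluster 4 (47, 4841, 75 and 220). The latter was mostly knockout naive. Dissection, loading and the filter can all set these shares. Among nuclei with at least 1000 UMIs and 500 genes, astrocyte-like shares were 2.83%, 3.44%, 4.05% and 2.33%, lowest in the knockout SNI library, and oligodendrocyte-like shares 1.999%, 7.61%, 2.78% and 1.53%. Single-library clustering gave oligodendrocyte-like shares of 15.2%, 18.4%, 10.6% and 18.4%, so neither order of libraries was stable. The endothelial cluster held 45 nuclei of the wild-type naive library, under the minimum of 50, so endothelial nuclei and the endothelial barrier list were not compared.

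**Figure D1:**
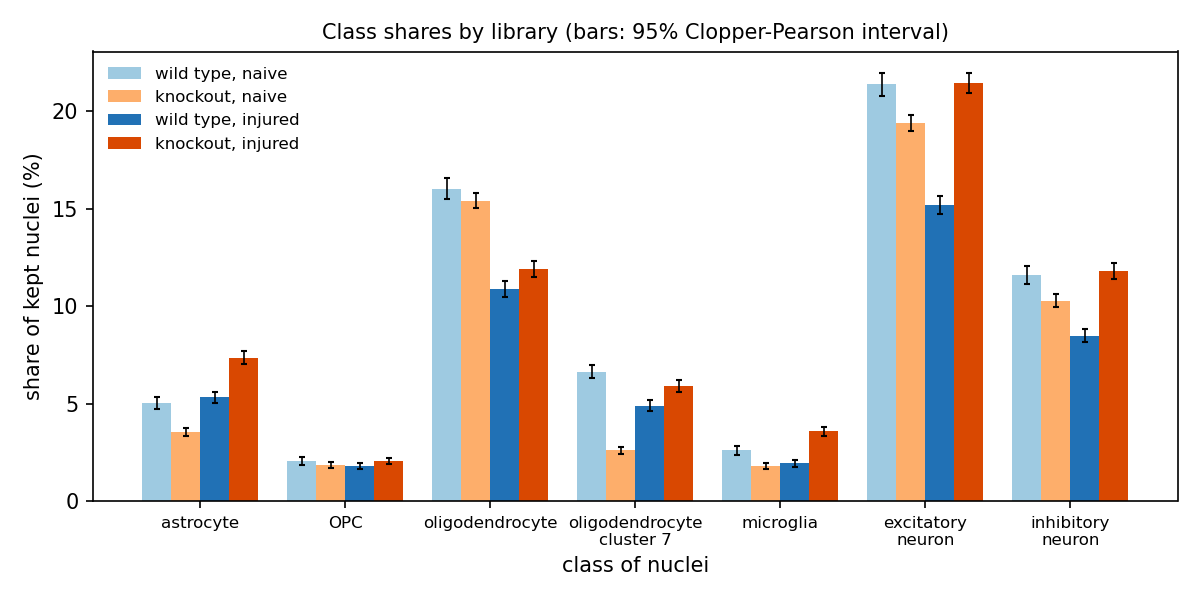
Share of kept nuclei (percent) in each named class for the 4 libraries, with bars for 95% Clopper-Pearson intervals that cover counting error only. Astrocyte- and microglia-like shares were highest in the knockout SNI library, the former not under every setting.

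Gpr37l1 transcripts were nearly gone from both knockout libraries, and in wild-type astrocyte-like nuclei they were at the same level with and without injury. Gpr37l1 (Ensembl ENSMUSG00000026424, chromosome 1, 135160234 to 135167681 in GRCm38) stood at 143, 0, 144 and 1.26 CPM in astrocyte-like nuclei, from 133, 0, 203 and 2 UMIs. The knockout was 65.7-fold lower in the naive pair with the count of 0 set to a floor of 3, and the upper 95% limit of that log2 ratio was -5.72. In the SNI pair it was 114-fold lower, a log2 ratio of -6.83 (-9.88 to -4.96). In wild type the SNI to naive log2 ratio was 0.00 (-0.32 to 0.33) in these nuclei but 0.81 (0.65 to 0.97) over all kept nuclei, with 1.06 in excitatory and 1.21 in inhibitory neurons, where the level was low. Precursor-like nuclei came next, at 72.96, 3.16, 76.2 and 7.14 CPM, ahead of oligodendrocyte-like nuclei at 21.2, 0.606, 28.8 and 0 CPM. The KO to WT log2 ratio in precursor-like nuclei was -4.53 (-6.87 to -2.86) in naive and -3.42 (-5.36 to -1.95) in SNI libraries. After each nucleus was thinned to 1000 UMIs, 11.02% of 381 wild-type naive astrocyte-like nuclei and 13.8% of 732 wild-type SNI nuclei held a Gpr37l1 UMI. In the knockout these were 0 of 797 naive nuclei, where 3 counts would give 0.376%, and 1 of 379 SNI nuclei. Excitatory neurons, which should lack the gene, gave a background of 0.929% and 2.01% in the wild-type libraries. Median depth before thinning was 1155 and 1209 UMIs in those astrocyte-like nuclei and 1547 and 1629 in the neurons. The related receptor Gpr37 (Ensembl ENSMUSG00000039904, chromosome 6, 25665878 to 25690729) kept its level in oligodendrocyte-like nuclei at 123, 120.0, 119.6 and 117 CPM, while in astrocyte-like nuclei it stood at 37.7, 72.8, 62.9 and 61.9 CPM, lowest in the wild-type naive library.

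**Figure D2:**
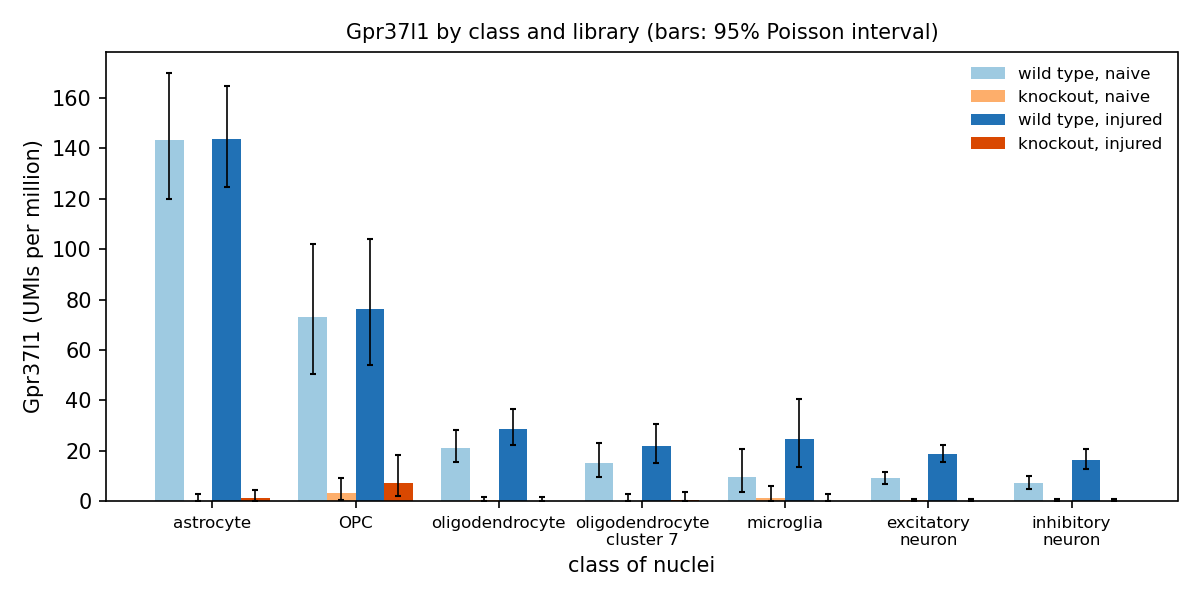
Gpr37l1 in CPM of the class total for each class and library, with bars for exact 95% Poisson intervals that cover counting error only. Gpr37l1 was highest in astrocyte-like nuclei of both wild-type libraries and at or near 0 in both knockout libraries.

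In astrocyte-like nuclei without injury, genes for taking up glutamate and GABA and for buffering potassium were lower in the knockout. They included the glutamate transporter Slc1a2, the GABA transporter Slc6a11, the glycine transporter Slc6a9 and the potassium channel Kcnj10. The cytokine gene Il18 and the glycolytic gene Eno1 were lower in both knockout libraries, and the phosphodiesterase genes Pde10a and Pde3b were higher in both. At 1 day after injury the uptake genes stood close to wild type, while genes of cholesterol synthesis were higher and clock and glucocorticoid-response genes lower in the knockout.

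The list of glutamate, GABA and potassium handling had a median KO to WT log2 ratio of -0.34 (-0.47 to -0.24) in naive libraries, with 13 of 14 members lower, at percentile 0.07 of random lists matched on expression. In SNI libraries its median was -0.06 (-0.13 to 0.04). Clustering each library on its own put the naive value at -0.69, and a coarser resolution the SNI value at -0.17. Slc6a11 had KO to WT log2 ratios of -0.69 (-0.86 to -0.52) in naive and -0.03 (-0.17 to 0.12) in SNI libraries, and Slc6a9 of -0.73 (-0.99 to -0.47) and -0.14 (-0.38 to 0.09). Slc1a2, the main glutamate transporter of astrocytes, stood at 2924, 2274, 2673 and 3071 CPM, and Kcnj10, which clears potassium, at 235, 163, 231 and 224 CPM. Atp1b2, a sodium pump subunit, stood at 359, 232, 399 and 352 CPM. Glul, which turns glutamate into glutamine, was the exception in the naive pair, higher in the knockout at 0.93 (0.65 to 1.20). Among genes by which astrocytes act on synapses, the median was -0.13 in naive (-0.49 with single-library clustering) and 0.04 in SNI libraries. Sparcl1, a secreted synaptogenic protein, was lower in the naive knockout at -0.56 (-0.68 to -0.43) and slightly higher in the injured at 0.13 (0.03 to 0.23), and the phagocytic receptor Mertk was lower in both at -0.55 and -0.31. Astrocyte marker genes summed to 3911, 3360.1, 3840.5 and 4171 CPM, so the markers that define the class were lowest in the naive knockout as well.

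Of genes with the same direction in both genotype contrasts, Il18 (Ensembl ENSMUSG00000039217, chromosome 9, 50554827 to 50581840), a cytokine of the interleukin-1 family, ranked first among the lower ones, at -0.84 (-1.13 to -0.56) and -0.90 (-1.19 to -0.61). It was followed by the noncoding Snhg9, Eno1 at -0.95 and -0.80, and Pdk2, a kinase that holds back pyruvate oxidation. The list continued with Pabpc4, Rwdd1, the hypoxia-related factor Hif3a, the cold-inducible RNA-binding gene Cirbp at -0.73 and -0.99, B3galt2 and 4930545L23Rik. Highest in the knockout were Pde3b, which breaks down cyclic AMP, at 1.249 (0.57 to 1.99) and 1.24 (0.69 to 1.81), and Rapgef5, an exchange factor for Rap proteins, at 1.20 and 1.13. Pde10a stood at 34.5, 195, 197 and 381 CPM, so it was lowest in the wild-type naive library and highest in the knockout SNI library. Ankrd44, Frmd4b, Man1a, Pdzd2, Zmat4, the calcium release channel Ryr3 and the secretory granule gene Ptprn2 were also higher in both. Ryr3, at 1.91 and 0.85, and Zmat4, at 2.28 and 0.91, are abundant in neurons, and general neuron markers summed to 2632, 6011, 3228 and 3551 CPM in astrocyte-like nuclei. Oligodendrocyte markers in the same nuclei summed to 1617, 2273, 1668 and 1689.9 CPM.

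Cholesterol synthesis genes were higher in the injured knockout as a group, with 16 of 16 members above wild type and a median of 0.43 (0.34 to 0.58), above all 10000 random lists, against 0.05 (-0.05 to 0.32) in the naive pair. Lss, which closes the sterol rings, was higher in both pairs at 1.21 (0.33 to 2.18) and 1.53 (0.74 to 2.38), as was Fdft1 at 0.45 and 0.70. Srebf2, which regulates the pathway, was higher in the SNI pair at 0.48. The glucocorticoid and circadian list had a median of -0.59 (-0.74 to -0.41) in the SNI pair, below all random lists, with 11 of 12 members lower, and of -0.14 (-0.36 to 0.04) in the naive pair. Single-library clustering put the naive medians of the 2 lists at -0.20 and -0.53. Within it the kinase Sgk1, induced by glucocorticoids, was higher in the naive knockout at 1.20 (0.60 to 1.84) and lower in the injured at -0.95 (-1.48 to -0.45). The clock repressors Nr1d1, at -1.21 and -0.84, and Nr1d2, at -0.35 and -0.68, and the clock output gene Dbp, at -0.57 and -1.01, were lower in both. Arntl, which encodes the clock activator BMAL1, went from -0.63 to 0.75. Times of day of tissue collection are not given in the sources used here.

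The list of GPR37 family members, the proposed ligand prosaposin, partners and receptors for pro-resolving lipids had medians of -0.44 and -0.02 in the naive and SNI pairs, which include Gpr37l1 itself; the naive one was -0.78 with single-library clustering and -0.21 without a UMI minimum. Psap, for prosaposin, stood at 0.69 (0.50 to 0.88) in naive and 0.09 (-0.06 to 0.24) in SNI libraries. The hedgehog receptor Ptch1 was lower in both at -0.44 and -0.34, and its partner Smo stood at -0.73 and 0.47. Lgr6, a proposed maresin receptor near Gpr37l1 on chromosome 1, was lower in the naive knockout at -1.19 (-1.62 to -0.77). Over the compared classes it stood at -0.98 (naive) and 0.20 (SNI). Cytokine, chemokine and NF-kB genes had medians of -0.24 and 0.11, or -0.65 and -0.32 after thinning, with Il33, an alarmin, at -0.80 and 0.09 and the NF-kB inhibitor gene Nfkbia at 0.54 and -0.68. Of the 24 genes of this list, 6 reached the minimum of 50 UMIs over a pair of libraries. Interferon response genes could be summarised in the SNI pair only, at 0.00, and immediate early genes likewise, at -0.03. Heat shock and unfolded protein genes had medians of 0.28 and -0.09; the naive value turned to -0.04 when each library was clustered on its own.

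**Figure D3:**
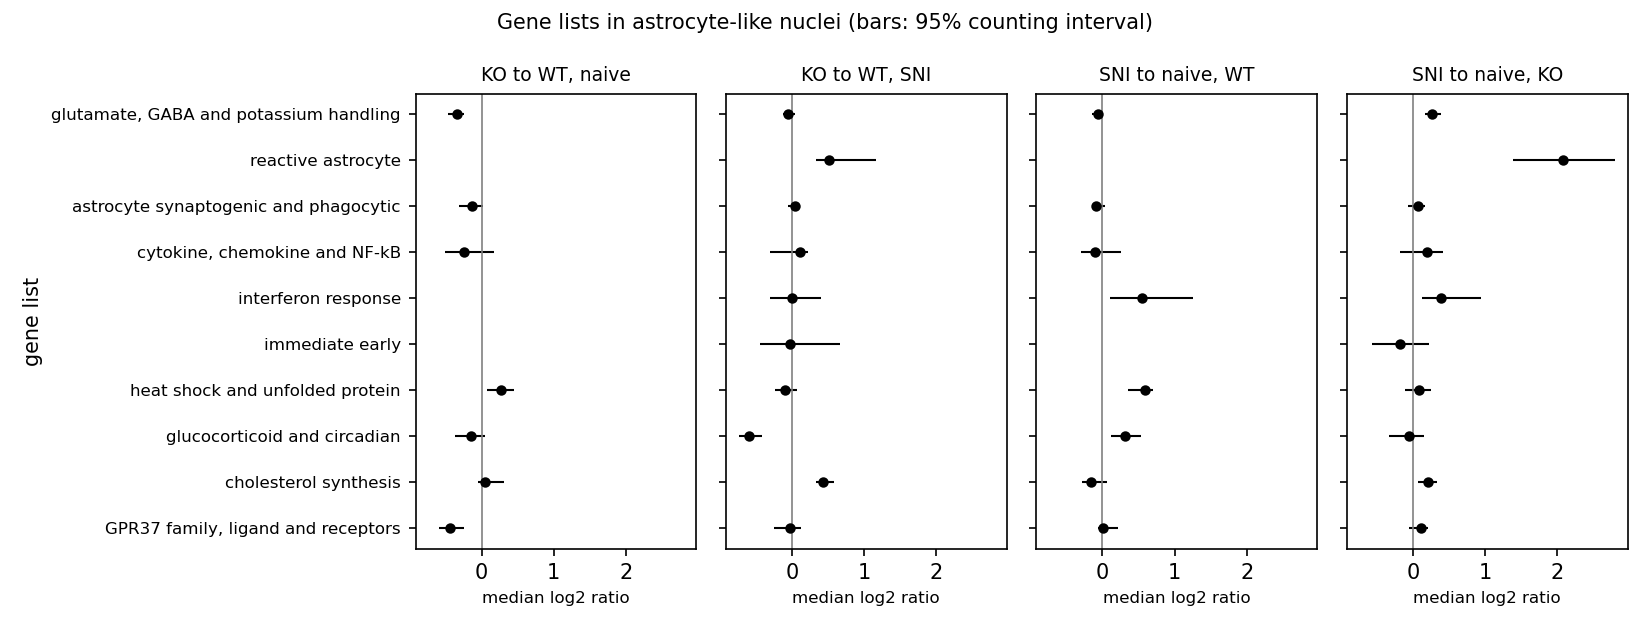
Median log2 ratio of each gene list in astrocyte-like nuclei for the 4 contrasts, with bars for 95% intervals from Poisson redraws of the counts; a list with fewer than 3 measured members in a contrast has no point. Glutamate, GABA and potassium handling was lower in the naive knockout.

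After injury, astrocyte-like nuclei of both genotypes held more Gfap, the intermediate filament gene that marks reactive astrocytes, and more Stat3, the factor that drives it. S100a10 and Serpina3n, also reactive genes, were higher mainly in the knockout. Transcripts for heat shock proteins were higher after injury in wild type, and glutamate and potassium handling genes were higher after injury in the knockout. Complement C1q transcripts, which come from microglia, were also higher in astrocyte-like nuclei of both injured libraries.

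Gfap (Ensembl ENSMUSG00000020932, chromosome 11, 102887336 to 102900912) stood at 43.1, 61.9, 124 and 166 CPM and was 2.87-fold higher after injury in wild type and 2.68-fold in the knockout, log2 ratios of 1.52 (1.02 to 2.05) and 1.42 (1.06 to 1.79). Stat3 was higher at 1.33 (0.92 to 1.75) and 0.69 (0.40 to 0.99). The complement gene C4b was higher than in naive nuclei at 2.94 (1.27 to 5.28) and 2.28 (1.30 to 3.42). S100a10, for an annexin-binding protein, stood at 8.63, 3.64, 19.8 and 80.2 CPM, Serpina3n, a protease inhibitor, at 5.39, 4.37, 12.7 and 45.5 CPM and the small heat shock gene Hspb1 at 2.16, 6.55, 9.90 and 27.8 CPM. The injury log2 ratio of S100a10 was 1.20 (0.03 to 2.54) in wild type and 4.46 (3.20 to 6.11) in the knockout, and that of Serpina3n 1.24 (-0.24 to 3.02) and 3.38 (2.19 to 4.87). Of 33 reactive genes, 7 reached 50 UMIs over the knockout libraries, with an injury median of 2.09 (1.38 to 2.80); the minimum sums both libraries, so it favours genes that are high in 1 of them. Only 2 reached it over the wild-type libraries and over the naive pair, so no median was taken there, and the KO to WT median in the SNI pair was 0.52 (0.34 to 1.16). S100a10 and Serpina3n were also highest in the knockout SNI library in each other class compared, such as excitatory neurons. Microglia markers in astrocyte-like nuclei summed to 315, 272, 467 and 944 CPM and cholinergic neuron markers to 2.16, 11.6, 23.3 and 82.8 CPM, both highest in the knockout SNI library.

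**Figure D4:**
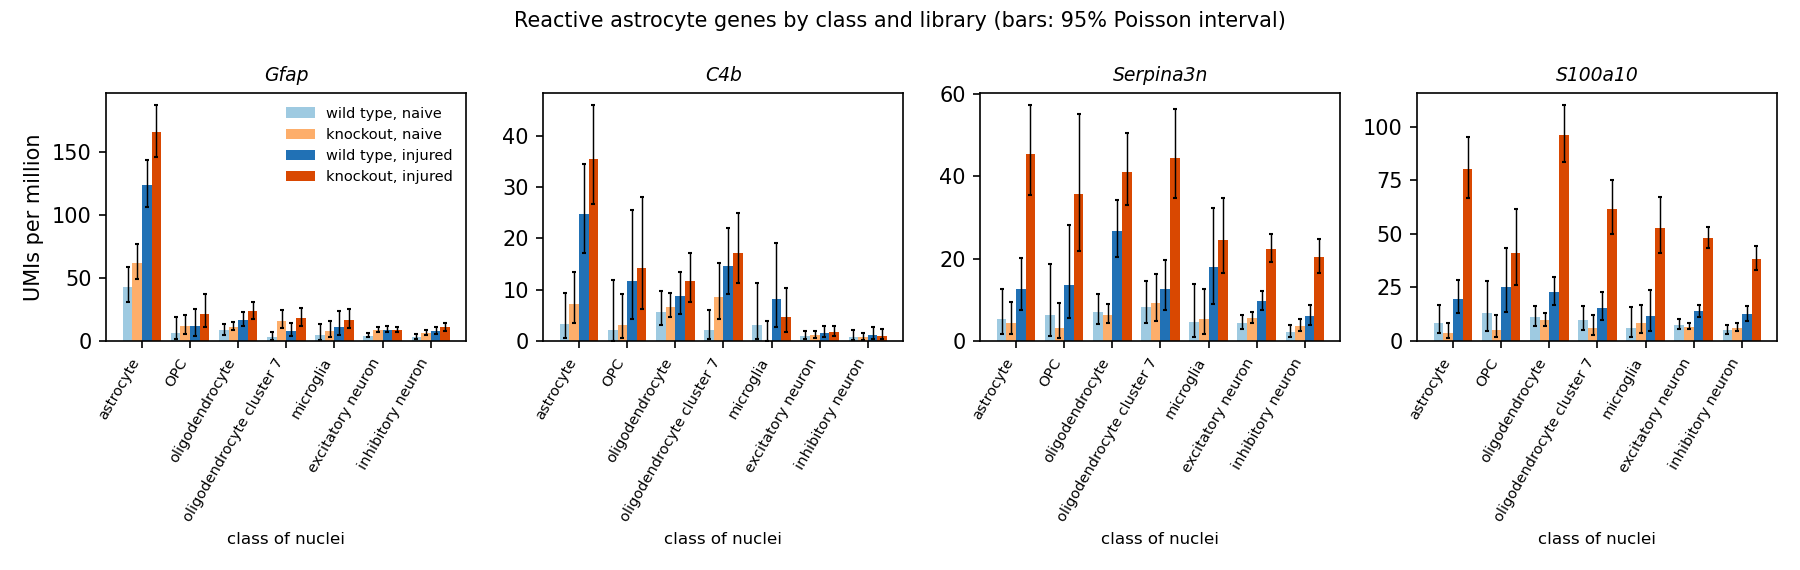
Gfap, C4b, Serpina3n and S100a10 in CPM of the class total for each class and library, with bars for exact 95% Poisson intervals that cover counting error only. Gfap was higher after injury in astrocyte-like nuclei of both genotypes, whereas Serpina3n and S100a10 were highest in the knockout SNI library in every class shown.

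Other genes higher after injury in both genotypes were C1qc, at 1.39 in wild type and 2.83 in the knockout, C1qb, the ribosomal gene Rps3a1 at 1.26 and 1.76, and the iron-storage gene Ftl1 at 0.98 and 1.095. The collagen gene Col23a1, the sodium pump regulator Fxyd7, the tubulin gene Tubb5 and Padi2 followed. Pde10a was higher at 2.52 and 0.97, the latter at -0.07 when each library was clustered on its own. Lower after injury in both were Csmd2, at -0.80 (-1.18 to -0.42) and -0.93 (-1.22 to -0.64), the adhesion gene Dscaml1 at -0.64 and -1.30, Sez6l, the actin regulator Evl, Trim24, Svil, Nelfb, the NF-kB kinase gene Ikbkb, Stx12 and the deacetylase gene Hdac9. Heat shock and unfolded protein genes had injury medians of 0.59 (0.36 to 0.70) in wild type, at percentile 99.99, and 0.08 (-0.11 to 0.25) in the knockout. The endoplasmic reticulum chaperone gene Hspa5 stood at 114, 154, 185 and 138 CPM, and Hspa8 had injury ratios of 0.48 and 0.31, the latter -0.0119 after thinning. Glucocorticoid and circadian genes were higher after injury in wild type, with a median of 0.31 (0.12 to 0.54), against -0.05 (-0.33 to 0.16) in the knockout. Cholesterol genes had medians of -0.15 and 0.21, interferon response genes of 0.55 and 0.39, cytokine genes of -0.10 and 0.20, and synaptogenic genes of -0.09 and 0.07. The GPR37 family list stayed near 0, at 0.00 and 0.11, and immediate early genes had a knockout median of -0.18. Single-library clustering put the knockout medians at 0.28 for heat shock, 0.20 for glucocorticoid and circadian, 0.49 for cholesterol, 0.25 for synaptogenic and 0.41 for GPR37 family genes, which narrows the contrast with wild type for the first 2, and thinning put cytokine genes at -0.38 and 0.50.

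The injury log2 ratio in the knockout minus that in wild type asks whether injury went with different genes in the 2 genotypes. It was positive for the uptake genes, with a list median of 0.43 (0.22 to 0.51) at percentile 99.99, and for cholesterol genes at 0.35 (0.11 to 0.54). The same difference was negative for glucocorticoid and circadian genes at -0.42 (-0.67 to -0.22), and lay at -0.16 for heat shock genes, 0.16 for synaptogenic genes, 0.17 for cytokine genes and 0.06 for the GPR37 family list. Single-library clustering put it at 0.80 for uptake, 0.59 for cholesterol, -0.12 for glucocorticoid and circadian, 0.28 for heat shock, 0.48 for synaptogenic and 0.30 for GPR37 family genes. Uptake genes were higher after injury in the knockout, with a median of 0.26 (0.17 to 0.39), and near 0 in wild type, at -0.06 (-0.14 to 0.01), or 0.08 at a coarser clustering resolution. Slc1a2, Kcnj10 and Atp1b2 were all lowest in the knockout naive library. In the same nuclei neuronal excitability genes had a difference of -0.85 (-1.00 to -0.64), below all random lists, and the neuron markers given above were highest in that library. The largest positive differences were in the noncoding Gm9925, Gm15520 and Gm31356, in Tmem100, a membrane gene of BMP signalling, and in Ccdc24. Gm31356 stood at 153, 37.1, 117 and 126 CPM and Tmem100 at 59.3, 26.2, 38.2 and 72.6 CPM, lowest in the knockout naive library. The largest negative differences were in Dach1, Fam189a1, Hs3st4, Etl4 and the kinesin gene Kif26b. Dach1 stood at 16.2, 103, 38.2 and 32.2 CPM and Etl4 at 62.5, 335, 103 and 102 CPM, highest in the knockout naive library. The wild-type injury ratios of Fam189a1, Etl4 and Kif26b turned negative at a coarser clustering resolution. Across 5089 genes the KO to WT ratios of naive and SNI libraries correlated at Pearson r 0.290 and Spearman rho 0.247, while injury ratios of the 2 genotypes correlated over 5088 at r -0.126, or 0.152 at the coarser resolution; genes are not independent replicates. Naive KO to WT ratios were spread more widely than those after injury, with standard deviations across genes of 0.588 and 0.3003.

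In oligodendrocyte-like nuclei, the troponin gene Tnni1, the zinc transporter gene Tmem163 and the aminopeptidase gene Rnpep were lower in both knockout libraries. After injury, the glucocorticoid-induced genes Sgk1 and Zbtb16 were higher in wild type and not in the knockout. Serpina3n was higher after injury in both.

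Tnni1 (Ensembl ENSMUSG00000026418, chromosome 1, 135779434 to 135810989), which lies on the chromosome of Gpr37l1 less than 1 Mb away, stood at 129, 5.86, 107 and 11.3 CPM, with KO to WT log2 ratios of -4.46 (-5.07 to -3.91) and -3.25 (-3.90 to -2.65). Tmem163 had ratios of -1.35 (-1.61 to -1.08) and -2.06 (-2.59 to -1.56), Rnpep of -1.17 and -1.33 and the GTPase gene Rhoj of -1.37 and -1.14. Hbb-bs, for haemoglobin of red blood cells, was also lower, at -2.28 and -1.70. Higher in both were the proton exchanger Slc9a7, at 1.33 and 1.23, Il1rapl2, Msrb3 and the cluster 7 leading genes 6030407O03Rik and Gm32122. Gm32122 was lower in the naive knockout, at -0.42, with at least 1000 UMIs and 500 genes. Sgk1 had injury ratios of 1.08 (0.86 to 1.30) in wild type and -0.59 (-0.82 to -0.36) in the knockout, and Zbtb16 of 0.93 (0.72 to 1.15) and -0.03 (-0.29 to 0.21). The glucocorticoid and circadian list had a KO to WT median of -0.55 (-0.79 to -0.22) in the SNI pair, below all random lists, against -0.06 in the naive pair, and injury medians of 0.27 and -0.17; Fkbp5 was lower in both knockout libraries at -0.36 and -0.80. The oligodendrocyte injury list had injury medians of 0.61 (0.32 to 0.92) in wild type and 0.29 (0.01 to 0.61) in the knockout, and KO to WT medians of -0.24 and -0.07. Serpina3n, its best-known member, had injury ratios of 1.91 (1.102 to 2.81) and 2.72 (2.11 to 3.35), and Nfkbia of 1.16 and -0.65. The knockout injury median of this list turned to -1.02 among nuclei with at least 1000 UMIs and 500 genes. C1qa, S100a10, Sncg, Sh3bgrl3 and Rps3a1 led the genes higher after injury in both, with S100a10 at 11.03, 9.69, 22.7 and 96.2 CPM, and Slc9a7, 6330562C20Rik, Zfp933 and Gm32122 were among the lower ones, the last at 0.86 in the knockout with single-library clustering.

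Heat shock genes in oligodendrocyte-like nuclei had injury medians of 0.39 (0.31 to 0.57) in wild type and 0.32 (0.06 to 0.39) in the knockout, the latter -0.13 in the deeper nuclei just named, and KO to WT medians of 0.45 and 0.01. Cholesterol genes, which oligodendrocytes need for myelin, had KO to WT medians of 0.24 and 0.07 and injury medians of 0.19 and 0.06. The GPR37 family list had KO to WT medians of -0.03 and -0.03 and injury medians of 0.39 and -0.05; Psap was higher in the naive knockout at 0.50 and Rora at 1.70 (1.56 to 1.85). Injury differences between genotypes were -0.67 (-0.96 to -0.39) for the injury list, -0.33 (-0.52 to -0.07) for heat shock, 0.00 for glucocorticoid and circadian, -0.13 for cholesterol and -0.27 (-0.47 to -0.14) for GPR37 family genes. In the deeper nuclei the glucocorticoid and circadian list had injury medians of 0.91 and 0.11 and a difference of -0.75, and the GPR37 family list a naive KO to WT median of 0.56; without a UMI minimum the difference of the latter was 0.00710. That of the injury list changed sign under 5 alternatives. Neuron markers in these nuclei summed to 2879.7, 6827, 3908 and 3984 CPM, and own markers to 15622, 12062, 13565 and 14701 CPM. Genotype ratios correlated at r 0.218 and injury ratios at r -0.198 across genes.

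In oligodendrocyte cluster 7, the kainate receptor gene Grik1 and the clock gene Arntl2 were far lower in both knockout libraries, and cholesterol genes were higher after injury in wild type. Grik1 stood at 865, 137, 626 and 101 CPM, with KO to WT log2 ratios of -2.65 (-2.89 to -2.43) and -2.63 (-2.88 to -2.38), and Arntl2 at 98.3, 10.8, 99.5 and 10.8 CPM, with ratios of -3.18 (-4.09 to -2.39) and -3.20 (-4.02 to -2.47). The noncoding 4930420G21Rik was lower at -4.02 and -2.71; it lies on chromosome 16, as does Grik1. Gm40578 and Rnpep were lower as well, and Fchsd2, at 1.76 and 1.30, the chondroitin synthase gene Chsy3, Man1a, Gulp1 and Pde3b were higher. Cholesterol genes had an injury median of 0.53 (0.36 to 0.66) in wild type, above all random lists, and 0.17 (0.01 to 0.29) in the knockout, the latter 0.00 after thinning, and KO to WT medians of 0.10 and -0.20 (-0.33 to -0.06). Glucocorticoid and circadian genes had KO to WT medians of 0.03 and -0.44 (-0.84 to -0.17) and injury medians of 0.34 and -0.19, with Sgk1 at 44.6, 72.6, 120.1 and 63.7 CPM. Members of the oligodendrocyte injury list had KO to WT medians of -0.13 and 0.35 and injury medians of -0.01 and 0.12; Klk6, a protease gene that marks mature oligodendrocytes of the cord, had injury ratios of -0.01 and 0.94 (0.52 to 1.38), and Serpina3n of 0.59 and 2.27. Higher after injury in both were C1qb, Rps3a1, Ftl1, Tubb5 and Rps4x, and lower Col16a1, at -0.74 and -1.65, Dpysl5, Padi2 and Hdac1. Injury differences between genotypes were -0.40 (-0.65 to -0.13) for cholesterol and -0.45 (-0.82 to 0.06) for glucocorticoid and circadian genes, the latter -0.92 after thinning. Genotype ratios correlated at r 0.276 and injury ratios at r -0.141, and neuron markers summed to 1664, 4716, 2381 and 2615 CPM.

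Precursor-like nuclei were too few for most lists, and their clearest group was cholesterol synthesis, which was higher in the naive knockout. All 11 measured members were higher there, with a median of 0.46 (0.16 to 0.80), and the SNI pair had a median of -0.16 (-0.48 to 0.21). Injury medians were 0.64 (0.18 to 1.00) in wild type and -0.07 (-0.38 to 0.12) in the knockout. The GPR37 family list had KO to WT medians of 0.02 and -0.17 and injury medians of 0.10 and -0.08. No member of the cell cycle list reached 50 UMIs over a pair of libraries, so it gave no median. Tmem163 was lower in both knockout libraries at -1.41 (-1.84 to -0.99) and -1.22 (-1.86 to -0.60), as were the cadherin gene Cdh19, Sycp2, 9630028H03Rik and Rab11fip2. Higher in both were the phosphodiesterase gene Pde11a, the glutamate receptor gene Grm8 at 1.82 and 0.92, Plcxd3, the potassium channel partner Kcnip4 at 1.24 and 0.82, and Clvs1; neuron markers summed to 9075, 12355, 8168 and 9038 CPM here and own markers to 11337, 7024, 11149 and 10268 CPM, lowest in the naive knockout. After injury, the ribosomal genes Rpsa and Rpl14, the ATP synthase gene Atp5j and Tubb5 were higher in both, and Il1rapl2, A330008L17Rik, Sgsm2, Rmst and Arhgap6 lower. The lower group was not stable: the wild-type ratio of Il1rapl2 was 0.06 with nuclei weighted equally, the knockout ratio of Arhgap6 was 0.10 after thinning, as that of Rmst was 0.12, and the wild-type ratio of A330008L17Rik was 0.20 with stricter doublet removal. Correlations across genes were r 0.275 for genotype and 0.108 for injury, the latter negative under 5 alternatives.

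Microglia-like nuclei of the naive knockout held less of P2ry12, Selplg and Siglech, which mark resting microglia, than any other library. Genes of activated microglia were also lower there than in naive wild type, so after injury both groups were higher in the knockout, while resting genes were lower after injury in wild type. The homeostatic list had a KO to WT median of -0.92 (-1.28 to -0.78) in the naive and 0.11 (-0.08 to 0.38) in the SNI pair, and injury medians of -0.71 (-0.98 to -0.54) in wild type and 0.36 (0.26 to 0.69) in the knockout. P2ry12, a receptor for ADP, stood at 449.9, 132, 275 and 255 CPM, Selplg at 389, 157, 199.8 and 204 CPM, Siglech at 422, 192, 236 and 335 CPM and Gpr34 at 175, 92.5, 54.05 and 97.8 CPM. The injury-activated list had KO to WT medians of -1.14 (-1.46 to -0.79) and 0.00 (-0.18 to 0.34) and injury medians of -0.24 (-0.54 to 0.07) and 0.97 (0.63 to 1.21). Thinning put the knockout injury medians of the 2 lists at 0.21 and 0.43. Spp1, for osteopontin, was higher after injury in both genotypes at 1.01 (0.02 to 2.05) and 1.58 (0.99 to 2.20), and the ATP receptor gene P2rx4, tied to pain after nerve injury, stood at 91.2, 41.96, 39.3 and 78.9 CPM. Trem2, Tyrobp and Irf8 had naive KO to WT ratios of -1.49, -1.94 and -1.14. The microglia markers themselves summed to 6362, 3086, 6268 and 6068 CPM and neuron markers to 10885, 14953, 11388 and 12515 CPM, so the markers of the class were lowest in the naive knockout as well. Interferon response genes had an injury median of 0.99 (0.32 to 1.40) in the knockout and a KO to WT median of -0.30 (-0.64 to 0.50) in the SNI pair, with B2m at 78.6, 26.9, 45.9 and 78.9 CPM. Cytokine, chemokine and NF-kB genes had KO to WT medians of -0.58 and -0.14 and injury medians of -0.30 and 0.19.

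Genes lower in both knockout libraries of microglia-like nuclei were Cryl1, Gcnt1, Suclg2, the phospholipase gene Pla2g4a, at -1.37 (-1.85 to -0.89) and -1.09 (-1.43 to -0.76), and Cables1, and genes higher in both were Rnf152, Csgalnact1, Ptprz1, Btbd11 and Lin7a. At a coarser clustering resolution, the SNI ratios of Gcnt1, Pla2g4a and Btbd11 changed sign, and the correlation of genotype ratios, r 0.310, was -0.333. Higher after injury in both genotypes were the neurofilament gene Nefm, Rps3a1, Tnfaip8, Atp6v0a2 and Sbno2, and lower were Gcnt1, 9530026P05Rik, Miga1, Fbxo3 and 5730522E02Rik; at the coarser resolution the wild-type ratios of Tnfaip8, 9530026P05Rik and 5730522E02Rik changed sign. Injury differences between genotypes were 1.49 (1.18 to 1.69) for the homeostatic and 1.21 (0.70 to 1.57) for the injury-activated list; injury ratios correlated at r -0.0944. At the coarser resolution the 2 lists had SNI genotype medians of 1.08 and 0.81 and wild-type injury medians of -1.41 and -0.90, and stricter doublet removal put the naive genotype medians at -1.63 and -1.71. In other classes the difference was 1.34 (1.104 to 1.94) in excitatory neurons and 0.75 in oligodendrocyte-like nuclei for the homeostatic list, and 0.89 in astrocyte-like and 0.62 in oligodendrocyte-like nuclei, 0.40 in excitatory and 0.16 (-0.11 to 0.45) in inhibitory neurons for the injury-activated list.

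In excitatory neurons, several peptide and receptor genes of the dorsal horn, among them Sst, Npy1r and Grpr, were lower in the naive knockout than in the naive wild type, and higher after injury in the knockout. Heat shock genes were higher after injury in wild type and less so in the knockout. Atf3, a gene switched on in neurons with damaged axons, was seen almost only in the injured knockout, but there in every class compared. The neuropeptide and receptor list had a KO to WT median of -0.33 (-0.40 to -0.22) in naive and -0.05 (-0.16 to 0.04) in SNI libraries, and injury medians of 0.08 (-0.02 to 0.17) in wild type and 0.28 (0.22 to 0.37) in the knockout. Sst, for somatostatin, had KO to WT ratios of -0.86 (-0.94 to -0.77) and -0.40 (-0.49 to -0.31). The itch receptor gene Grpr stood at 16.4, 6.04, 10.5 and 12.4 CPM and Npy1r at 39.5, 22.98, 31.2 and 36.4 CPM, and Gal was higher after injury in both genotypes at 0.81 and 0.74, as was Npy at 0.69 and 0.20. Excitatory neuron markers summed to 1954, 1665, 1786 and 1859.8 CPM. Heat shock genes had injury medians of 0.42 (0.37 to 0.67) and 0.18 (0.10 to 0.25), the latter 0.0212 after thinning, and KO to WT medians of 0.28 and -0.07; Hspa5 had injury ratios of 0.65 and 0.11. Immediate early genes had KO to WT medians of 0.28 and 0.06 and injury medians of 0.53 and -0.03, with Egr1 at 12.4, 16.9, 17.9 and 12.4 CPM. Atf3 had 3, 2, 5 and 75 UMIs in these nuclei, an injury log2 ratio of 5.92 (4.01 to 8.99) in the knockout; at 9.61 CPM it was lower in them than in astrocyte-like nuclei, at 13.9, or oligodendrocyte-like nuclei, at 23.04, of that library. The excitability list stayed near 0, with KO to WT medians of 0.05 and 0.06 and injury medians of -0.03 and 0.00.

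Within the excitability list of excitatory neurons, the glutamate receptor gene Gria4 was higher in the naive knockout at 0.55 (0.50 to 0.59) and Gria2 lower at -0.41 (-0.44 to -0.38); the chloride importer gene Slc12a2 was higher at 0.64 and the sodium channel gene Scn8a at 0.45. In the SNI pair they stood at 0.06, -0.12, 0.16 and -0.10, the first at -0.0739 with single-library clustering. Of genes with the same direction in both contrasts, Lgals1 had injury ratios of 1.48 (0.33 to 2.76) in wild type and 4.27 (3.51 to 5.14) in the knockout, followed by Sncg at 1.39 and 2.34, Msn, Jun and Hspb1. Lgals1, Sncg and Hspb1 are abundant in sensory and motor neurons, and cholinergic neuron markers summed to 6.95, 6.68, 12.4 and 45.5 CPM here. Lower after injury were Gm41804, Gm5136, Gm43774, Zfp933 and A230001M10Rik, the last at 0.32 in the knockout with single-library clustering. Lower in both knockouts were Hbb-bs, at -2.81 and -1.61, Zbed5, Scpep1os, Mycbpap and, as in astrocyte-like nuclei, Pabpc4, at -1.097 and -0.82. Higher in both were A330049N07Rik, which like A230001M10Rik leads oligodendrocyte clusters, Mertk, Lama2, Zfp36l1 and Lhfpl2. Injury differences between genotypes were 0.08 (-0.01 to 0.26) for peptides and receptors, -0.31 (-0.43 to -0.17) for heat shock, -0.39 for immediate early and 0.01 for excitability genes. Correlations across genes were r 0.189 for genotype and -0.0689 for injury.

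In inhibitory neurons, the mu-opioid receptor gene Oprm1 was lower and the calcium channel subunit gene Cacna2d1, the target of gabapentin, was higher in the naive knockout, and heat shock genes were higher after injury in both genotypes. Oprm1 had KO to WT log2 ratios of -0.91 (-1.06 to -0.75) in naive and 0.02 (-0.15 to 0.19) in SNI libraries, and Cacna2d1 of 1.16 (1.02 to 1.30) and 0.41 (0.25 to 0.57). Sst was lower in both at -0.52 and -0.17, and Slc12a2 higher at 0.78 and 0.26. Gal had injury ratios of 0.63 in wild type and 0.68 in the knockout, the latter -0.52 when each library was clustered on its own, and Npy of 0.50 and 0.20. The neuropeptide and receptor list had KO to WT medians of 0.03 and -0.07 and injury medians of 0.08 and 0.20, the last 0.00 with single-library clustering. Heat shock genes had injury medians of 0.46 (0.34 to 0.59) and 0.19 (0.11 to 0.29) and KO to WT medians of 0.25 and 0.01. Immediate early genes had KO to WT medians of 0.12 and 0.02 and injury medians of 0.06 and 0.04. Excitability genes had KO to WT medians of 0.06 and 0.06 and injury medians of -0.04 and -0.06. Lower in both knockout libraries were Hbb-bs, 9330175M20Rik, Tmc4, Gm34552 and Scpep1os. Higher in both were the cholesterol exporter gene Abca1, Dusp26, Grn and the astrocyte markers Gja1 and Aqp4, and astrocyte markers together summed to 413, 302, 398 and 425 CPM. S100a10, C1qa, Rps3a1, Rplp0 and Fcer1g were higher after injury in both, with microglia markers at 197, 162, 253 and 507 CPM, and Gm41804, Snhg3, Pkdcc, Ciao1 and Traip lower. Injury differences between genotypes were -0.17 for peptides and receptors, -0.32 (-0.46 to -0.14) for heat shock, 0.03 for immediate early and -0.01 for excitability genes, and correlations across genes were r 0.198 for genotype and -0.0611 for injury.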

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

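The tests of strain DNA, of differing free RNA near Gpr37l1, of a single library standing apart, of gene length, of S100a10 and Serpina3n, of free RNA for Tnni1 and both tests of uptake genes alone, with their bounds, were chosen only after the results they concern were seen; the others were set beforehand. The results collected here are those whose 2 genotype or 2 injury ratios had counting intervals on opposite sides of 0, and 3 patterns are weighed first.

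Several genes around Gpr37l1 on chromosome 1 were lower in both knockout libraries, with Tnni1 at -3.77 and -3.20 in naive and SNI libraries over the compared classes, Rnpep at -0.75 and -0.54, Klhl12 at -0.74 and -0.50 and Shisa4 at -1.21 and -0.36. Of 83 genes measured within 5 Mb, 30 were lower in both, 23 higher in both and 30 differed in sign. DNA of another mouse strain carried along with the targeted locus could do this, but as a set these genes stood only at percentile 89.9 of random lists, short of the bound of 95, and a shorter block around Tnni1 was not tested. Free RNA that differs by chance between libraries would give no relation between the 2 genotype contrasts; across these genes they correlated at r 0.511, but at 0.157 without Tnni1, so for the set it cannot be told apart from a genotype effect. For Tnni1 free RNA is argued against, since the loss in oligodendrocyte-like nuclei was at least 12.7 times the mean loss of the other classes in both pairs. A direct effect of the targeted allele on its neighbours stays open and was not tested.

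In astrocyte-like nuclei the injury ratios differed between genotypes, with uptake genes higher after injury in the knockout and not in wild type. A single library standing apart may be behind much of it: ratios that involve the knockout naive library were at least 1.44 times as widely spread across genes as the KO to WT ratios after injury. For the uptake genes RNA of other cells that dilutes astrocyte transcripts is also in keeping with the values, as summed astrocyte markers had 0.778 of their difference and neuronal excitability genes a difference of -0.85. Uptake genes had a mean difference of -0.270 in the other 6 classes, for which their list is not meant, so a shared shift stays open. Over all genes the differences correlated with those of inhibitory neurons at r 0.404 over 4881 genes, with gene length at r -0.215 over 5088 genes and with enrichment in the cytoplasm-like cluster 1 at r -0.101. There a shared library shift, a different share of unspliced RNA, and free cytoplasmic RNA cannot be told apart from a genotype-dependent response, because each group has 1 library and the correlations are neither absent nor large. Whether injury acts differently in knockout astrocytes therefore stays open.

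Gfap and other reactive astrocyte genes were higher after injury. RNA of other cells in every droplet would raise a gene alike in all classes, and the gain of Gfap in astrocyte-like nuclei was 13.9 times the mean gain of the other classes in wild type and 16.9 times in the knockout, which argues against it for Gfap. For S100a10 and Serpina3n in the knockout the gains were 1.55 and 1.59 times those of the other classes, so free RNA and a rise within astrocytes cannot be told apart: both genes were higher in all classes of that library. An astrocyte response to nerve injury is thus a hypothesis that the Gfap values are consistent with, from the data in which it was noticed. Whether it depends on Gpr37l1 was not tested.

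The remaining results are given as the injury log2 ratio in the knockout minus that in wild type, and none of these differences was tested. In astrocyte-like nuclei the injury ratios had opposite directions for Gm9925 (2.31), Gm31356 (2.15), Ccdc24 (2.06), Slc6a11 (0.66), Dach1 (-2.92), Fam189a1 (-2.81), Hs3st4 (-2.75), Etl4 (-2.44) and Kif26b (-2.44). Genotype ratios there had opposite directions in naive and SNI libraries for Sparcl1 (0.68), Hspa5 (-0.85) and Smo (1.20). Both kinds of ratio did for Tmem100 (2.11), Slc1a2 (0.56), Sgk1 (-2.15) and Arntl (1.38). At resolution 0.5 the wild-type injury ratios of Slc1a2, Fam189a1, Etl4 and Kif26b changed sign, which ended their opposite injury directions. In oligodendrocyte-like nuclei injury ratios were opposite for Tnni1 (1.22) and Rora (-1.65), genotype ratios for C1qa (1.07), and both for Sgk1 (-1.67) and Nfkbia (-1.81). Oligodendrocyte cluster 7 had opposite injury ratios for 4930420G21Rik (1.31) and opposite genotype ratios for Sgk1 (-1.62). In microglia-like nuclei the homeostatic list had opposite injury medians, a difference of 1.49, as had its members P2ry12 (1.66) and Selplg (1.34), while Gpr34 (1.77) had opposite genotype ratios and Siglech (1.65), P2rx4 (2.12) and B2m (2.33) both. Excitatory neurons had opposite injury ratios for Npy1r (1.00), Grpr (1.68), Gria4 (-0.49), Gria2 (0.30) and Scn8a (-0.54), opposite genotype ratios for Zfp933 (-1.17) and Hspa5 (-0.54), and both for Egr1 (-0.97). Nts (1.02) had opposite genotype ratios but leads an excitatory cluster, so it is no result. The knockout injury ratio of Gria2 fell to 0 with TMM factors. In inhibitory neurons injury ratios were opposite for Oprm1 (0.93) and Slc12a2 (-0.52), and genotype ratios for Hspa5 (-0.54).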

How the results depend on the processing

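Single oligodendrocyte clusters were tested only for Tnni1, Rnpep and Tmem163, after the results were seen. Every other alternative was planned. In cluster 2 alone the naive and SNI genotype ratios were -4.36 and -3.16 for Tnni1, -2.32 and -1.26 for Rnpep and -2.81 and -2.15 for Tmem163, and in cluster 4 alone -1.54 and -2.24 for Rnpep, -1.19 and -2.02 for Tmem163 and -2.18 for Tnni1 in the naive pair, so all stayed lower in the knockout. No paired analysis was possible because each group has 1 library. The alternatives kept the sign of 9348 of 9756 gene ratios, 1440 of 1594 list medians, 158 of 166 correlations and 172 of 176 shares. The 4 others were shares of 0 for cluster 7, a label unused in single-library clustering. Its genes and lists have no value there. In knockouts nuclei like cluster 7 joined oligodendrocytes. Within counting error stayed 9181 gene ratios, 1467 list medians, 80 correlations and 67 shares, while 534 gene ratios moved beyond it. Few UMIs per gene limit the lists in precursors and microglia. TMM factors shifted the median of all genes by 0.112 and 0.111 in microglia (naive and SNI genotype ratios), -0.105 in oligodendrocyte cluster 7 (naive genotype) and -0.102 in excitatory neurons (KO injury), and DESeq2 factors by under 0.1 everywhere. Values that moved or reversed follow, with class names short for class-like nuclei, list names shortened, medians and ratios in log2, WT for wild type, KO for knockout, and shares in the order WT naive, KO naive, WT SNI and KO SNI; the cause was not tested.

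Single-library clustering put naive genotype medians at -0.69 for uptake, -0.49 for synaptogenic, -0.58 for cytokine, -0.0377 for heat shock, -0.53 for glucocorticoid, -0.20 for cholesterol and -0.78 for GPR37 family in astrocytes and -0.45 for neuropeptide in excitatory neurons. It put KO injury medians at 0.59 for uptake, 0.25 for synaptogenic, 0.28 for heat shock, 0.20 for glucocorticoid, 0.49 for cholesterol and 0.41 for GPR37 family in astrocytes, 0.77 for injury list in oligodendrocytes and -0.00250 for neuropeptide in inhibitory neurons. It put SNI genotype medians at -0.23 for heat shock and 0.34 for injury list in oligodendrocytes and 0.14 for excitability in inhibitory neurons. It put injury differences at 0.80 for uptake, 0.48 for synaptogenic, 0.28 for heat shock, -0.12 for glucocorticoid, 0.59 for cholesterol and 0.30 for GPR37 family in astrocytes, 0.29 for injury list in oligodendrocytes and 0.0418 for excitability in inhibitory neurons. It gave genotype correlations of 0.247 in astrocytes, 0.289 in oligodendrocytes, 0.205 in microglia, 0.234 in excitatory neurons and 0.166 in inhibitory neurons. It gave injury correlations of -0.220 in oligodendrocytes, 0.182 in precursors and -0.0925 in excitatory neurons. It moved KO injury ratios to -0.0710 for Pde10a and 0.19 for Gpc5 in astrocytes, 0.86 for Gm32122 in oligodendrocytes, 0.32 for A230001M10Rik in excitatory neurons and -0.52 for Gal in inhibitory neurons. It moved SNI genotype ratios to -0.0739 for Gria4 in excitatory neurons. It gave shares of 4.65% (KO naive) of astrocytes and 15.2% (WT naive), 18.4% (KO naive) and 18.4% (KO SNI) of oligodendrocytes. Precursors had 2.51% (WT naive), 2.21% (KO naive) and 2.07% (WT SNI), and microglia 3.48, 2.62, 2.57 and 5.05%. Excitatory neurons had 19.8, 24.01, 16.5 and 26.5%, and inhibitory neurons 12.02% (KO naive), 9.32% (WT SNI) and 9.86% (KO SNI).

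Resolution 0.5 put SNI genotype medians at -0.17 for uptake in astrocytes and 0.19 for cytokine, 1.08 for homeostatic and 0.81 for injury-activated in microglia. It put WT injury medians at 0.0834 for uptake and 0.0495 for synaptogenic in astrocytes and -1.41 for homeostatic and -0.90 for injury-activated in microglia. It put injury differences at 0.29 for injury list in oligodendrocytes and 2.09 for homeostatic and 1.77 for injury-activated in microglia. Genotype correlations were 0.349 in astrocytes, 0.199 in oligodendrocytes and -0.333 in microglia. Injury correlations were 0.152 in astrocytes and -0.453 in microglia. It moved WT injury ratios to -0.47 for Fam189a1, -0.49 for Etl4, -0.30 for Kif26b and 0.0102 for Slc1a2 in astrocytes and -0.25 for Suclg2, -0.21 for Pla2g4a, -0.00447 for Tnfaip8, 0.0194 for 9530026P05Rik and 0.52 for 5730522E02Rik in microglia. It moved SNI genotype ratios to -0.00623 for Btbd11, 0.20 for Gcnt1, 0.0160 for Pla2g4a, 0.34 for Rps3a1, 0.13 for Tnfaip8 and -0.23 for 5730522E02Rik in microglia. It gave shares of 5.81, 4.55, 5.82 and 8.52% of astrocytes, 17.5% (WT naive), 11.8% (WT SNI) and 12.7% (KO SNI) of oligodendrocytes, 3.68, 2.53, 3.26 and 5.33% of microglia.

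Deeper nuclei put WT injury medians at -0.33 for cytokine in astrocytes and 0.91 for glucocorticoid in oligodendrocytes. They put naive genotype medians at 0.48 for heat shock in astrocytes and 0.56 for GPR37 family in oligodendrocytes. They put KO injury medians at -0.14 for heat shock and 0.0407 for cholesterol in astrocytes, -0.13 for heat shock, 0.11 for glucocorticoid, -0.17 for cholesterol and -1.02 for injury list in oligodendrocytes and 0.56 for injury-activated in microglia. They put SNI genotype medians at -0.75 for glucocorticoid in astrocytes, -0.28 for heat shock in oligodendrocytes and -0.16 for heat shock in excitatory neurons. They put injury differences at 0.19 for GPR37 family in astrocytes and -0.60 for heat shock, -0.75 for glucocorticoid and -0.32 for cholesterol in oligodendrocytes. They gave genotype correlations of 0.318 in astrocytes, 0.273 in oligodendrocytes and 0.238 in precursors. They gave injury correlations of -0.205 in cluster 7, -0.180 in oligodendrocytes, -0.110 in precursors, -0.0262 in microglia and -0.0932 in excitatory neurons. They moved naive genotype ratios to -5.43 for Gpr37l1 in astrocytes and -0.42 for Gm32122 in oligodendrocytes. They moved KO injury ratios to 0.18 for Il1rapl2 and -0.0828 for Hsph1 in oligodendrocytes and 0.0533 for Pde11a and 0.11 for Kcnip4 in precursors. They gave shares of 5.45% (WT naive), 3.39% (KO naive) and 4.17% (KO SNI) of cluster 7, 2.83% (WT naive), 4.05% (WT SNI) and 2.33% (KO SNI) of astrocytes, 1.999, 7.61, 2.78 and 1.53% of oligodendrocytes, 1.01, 1.62, 0.935 and 0.892% of precursors, 1.49, 1.18, 0.984 and 2.55% of microglia, 26.4, 26.1, 18.98 and 25.04% of excitatory neurons, 15.6, 14.2, 10.9 and 15.96% of inhibitory neurons.

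Thinning put WT injury medians at -0.16 for synaptogenic and -0.38 for cytokine in astrocytes and 0.74 for glucocorticoid in oligodendrocytes. It put naive genotype medians at -0.33 for glucocorticoid in cluster 7, -0.65 for cytokine in astrocytes and 0.43 for GPR37 family in oligodendrocytes. It put SNI genotype medians at -0.32 for cytokine in astrocytes, -0.26 for heat shock and -0.87 for glucocorticoid in oligodendrocytes and -0.0921 for homeostatic in microglia. It put KO injury medians at -0.00247 for cholesterol in cluster 7, 0.50 for cytokine, 0.0463 for cholesterol and 0.21 for GPR37 family in astrocytes, -0.16 for heat shock, 0.16 for glucocorticoid, -0.18 for GPR37 family and -0.73 for injury list in oligodendrocytes, 0.21 for homeostatic and 0.43 for injury-activated in microglia and -0.19 for immediate early and 0.0212 for heat shock in excitatory neurons. It put injury differences at -0.92 for glucocorticoid in cluster 7, 0.59 for uptake and 0.27 for synaptogenic in astrocytes, -0.70 for heat shock and -0.49 for GPR37 family in oligodendrocytes, 1.06 for homeostatic in microglia and -0.44 for heat shock in excitatory neurons. Genotype correlations were 0.209 in cluster 7, 0.290 in oligodendrocytes, 0.382 in precursors, 0.490 in microglia and 0.222 in excitatory neurons. Injury correlations were -0.203 in cluster 7, -0.146 in precursors, 0.0613 in microglia and -0.0360 in inhibitory neurons. It moved naive genotype ratios to -4.94 for Gpr37l1 in astrocytes. It moved KO injury ratios to -0.0580 for Slc1a3, 0.0208 for Gpc5 and -0.0119 for Hspa8 in astrocytes, -0.15 for Hsph1 in oligodendrocytes and 0.59 for Pde11a, 0.10 for Kcnip4, 0.12 for Rmst and 0.0970 for Arhgap6 in precursors. It moved SNI genotype ratios to -0.26 for Hsph1 in oligodendrocytes and 0.000985 for Rps3a1 in microglia.

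Stricter doublet removal put KO injury medians at 0.49 for cytokine and 1.24 for injury-activated in microglia. It put naive genotype medians at -1.63 for homeostatic and -1.71 for injury-activated in microglia. It put WT injury medians at -1.22 for homeostatic in microglia. It put injury differences at 2.08 for homeostatic in microglia. It gave genotype correlations of 0.224 in cluster 7, 0.246 in astrocytes, 0.200 in oligodendrocytes, 0.137 in precursors and 0.372 in microglia. It gave injury correlations of -0.171 in cluster 7, -0.197 in astrocytes, -0.227 in oligodendrocytes, -0.253 in precursors, -0.550 in microglia and -0.0870 in excitatory neurons. It moved WT injury ratios to 0.20 for A330008L17Rik and 0.00814 for Rmst in precursors and 0.84 for 5730522E02Rik in microglia. It gave shares of 7.84, 2.84, 5.47 and 6.59% of cluster 7, 5.95, 3.803, 5.93 and 8.12% of astrocytes, 18.9, 16.02, 12.1 and 13.2% of oligodendrocytes, 2.26% (WT naive) and 3.12% (KO SNI) of microglia, 22.99% (WT naive), 16.1% (WT SNI) and 22.4% (KO SNI) of excitatory neurons, 12.9% (WT naive), 9.01% (WT SNI) and 12.5% (KO SNI) of inhibitory neurons.

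Keeping doublets put injury differences at 0.32 for injury list in oligodendrocytes. Genotype correlations were 0.253 in cluster 7, 0.249 in astrocytes, 0.203 in oligodendrocytes and 0.207 in excitatory neurons. Injury correlations were -0.185 in cluster 7, -0.203 in astrocytes, -0.253 in oligodendrocytes, 0.0306 in precursors and -0.140 in microglia. It gave shares of 2.34% (KO naive), 4.52% (WT SNI) and 5.47% (KO SNI) of cluster 7, 3.36% (KO naive) and 6.99% (KO SNI) of astrocytes, 14.7% (KO naive) and 11.5% (KO SNI) of oligodendrocytes, 3.85% (KO SNI) of microglia, 18.6% (KO naive), 14.5% (WT SNI) and 20.4% (KO SNI) of excitatory neurons, 9.62% (KO naive), 7.89% (WT SNI) and 10.96% (KO SNI) of inhibitory neurons.

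Every barcode put injury differences at 0.33 for injury list in oligodendrocytes. It gave genotype correlations of 0.254 in cluster 7, 0.247 in astrocytes and 0.207 in excitatory neurons. It gave injury correlations of -0.184 in cluster 7, -0.203 in astrocytes, -0.252 in oligodendrocytes, 0.0255 in precursors and -0.135 in microglia. It gave shares of 2.34% (KO naive), 4.51% (WT SNI) and 5.45% (KO SNI) of cluster 7, 3.36% (KO naive) and 6.98% (KO SNI) of astrocytes, 14.8% (KO naive) and 11.5% (KO SNI) of oligodendrocytes, 3.99% (KO SNI) of microglia, 18.5% (KO naive), 14.4% (WT SNI) and 20.3% (KO SNI) of excitatory neurons, 9.61% (KO naive), 7.86% (WT SNI) and 10.9% (KO SNI) of inhibitory neurons.

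No UMI minimum put KO injury medians at -0.0850 for synaptogenic and 0.21 for GPR37 family in astrocytes, 0.48 for GPR37 family and 0.78 for injury list in oligodendrocytes and 0.76 for GPR37 family in precursors. It put WT injury medians at 0.67 for injury list in cluster 7, 0.70 for heat shock in astrocytes and 0.15 for injury-activated in microglia. It put naive genotype medians at -0.21 for GPR37 family in astrocytes. It put injury differences at -0.65 for heat shock in astrocytes and 0.00710 for GPR37 family and 0.32 for injury list in oligodendrocytes. Genotype correlations were 0.0794 in cluster 7, 0.0843 in astrocytes, 0.0725 in oligodendrocytes, 0.0282 in precursors, 0.0570 in microglia, 0.0636 in excitatory neurons and 0.0621 in inhibitory neurons. Injury correlations were -0.0158 in cluster 7, -0.0437 in astrocytes, -0.0364 in oligodendrocytes, -0.00770 in precursors, -0.0537 in microglia, -0.0338 in excitatory neurons and -0.0197 in inhibitory neurons.

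The 500-UMI minimum put KO injury medians at 0.31 for heat shock in astrocytes and 0.15 for glucocorticoid in oligodendrocytes. It put naive genotype medians at -0.21 for GPR37 family in astrocytes, 0.12 for heat shock, -0.42 for glucocorticoid, 0.34 for cholesterol and 0.23 for GPR37 family in oligodendrocytes and -0.43 for neuropeptide in excitatory neurons. It put SNI genotype medians at -0.80 for glucocorticoid in oligodendrocytes. It put WT injury medians at 0.59 for glucocorticoid in oligodendrocytes. It put injury differences at -0.89 for glucocorticoid in oligodendrocytes. It gave genotype correlations of 0.383 in cluster 7, 0.358 in astrocytes, 0.325 in oligodendrocytes, 0.431 in precursors, 0.461 in microglia, 0.269 in excitatory neurons and 0.254 in inhibitory neurons. It gave injury correlations of -0.249 in oligodendrocytes, 0.151 in precursors and -0.0373 in inhibitory neurons.

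Equal weights gave genotype correlations of 0.233 in cluster 7, 0.248 in astrocytes and 0.195 in oligodendrocytes. Injury correlations were -0.00214 in precursors. They moved WT injury ratios to 0.0581 for Il1rapl2 in precursors.

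TMM factors put KO injury medians at 0.0808 for heat shock, 0.17 for neuropeptide and -0.0993 for excitability in excitatory neurons and -0.14 for excitability in inhibitory neurons. They put naive genotype medians at 0.15 for excitability in excitatory neurons. They put injury differences at -0.0673 for excitability in inhibitory neurons. They moved KO injury ratios to -0.0000322 for Gria2 in excitatory neurons.

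DESeq2 factors put KO injury medians at 0.0852 for heat shock, 0.18 for neuropeptide and -0.0948 for excitability in excitatory neurons and -0.14 for excitability in inhibitory neurons. They put naive genotype medians at 0.13 for excitability in excitatory neurons.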

Other observations

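No hypothesis beyond those already weighed was tested, and no tests are reported in this part. Red blood cell RNA differed between genotypes in several classes. Hbb-bs, for beta haemoglobin, stood at 45.02, 9.29, 49.7 and 15.4 CPM in oligodendrocyte-like nuclei, 22.9, 3.26, 23.1 and 7.56 in excitatory and 17.5, 3.17, 19.8 and 6.78 in inhibitory neurons, in the order wild-type naive, knockout naive, wild-type SNI and knockout SNI. An unnamed cluster led by haemoglobin genes held 139, 103, 493 and 91 nuclei, most of them in the wild-type SNI library. A further unnamed cluster of 478 nuclei held 16, 10, 282 and 170, almost all from the SNI libraries, and passed the marker rule of no class.

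Nuclei of classes without gene comparisons also differed in number. Endothelial nuclei numbered 45, 167, 237 and 167, ependymal nuclei 49, 136, 148 and 92, nuclei of pericytes or smooth muscle 35, 162, 79 and 113 and those of fibroblasts or meninges 46, 194, 103 and 96. Committed oligodendrocyte precursors, which carry markers such as Bcas1 and Enpp6, numbered 198, 203, 179 and 214. Malat1, a nuclear RNA, took 9.09%, 4.38%, 8.27% and 6.30% of all UMIs, lowest in the knockout naive library. Cholinergic neuron markers were highest in the knockout SNI library in each class compared, at 13.7, 10.1, 25.3 and 93.5 CPM in oligodendrocyte-like nuclei and 6.29, 7.53, 19.7 and 44.9 CPM in microglia-like nuclei.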
